A study of Arachis hypogaea with 30 samples.

How the data were processed

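The data are gene counts and FPKM values from poly(A) RNA of whole peanut seedlings, 30 libraries in 10 groups of 3 (2 cultivars at 0 h in water and at 3, 12, 24 and 48 h in 100 mM NaCl). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, mRNA was captured with oligo-dT beads, primed at random and sequenced as paired reads. Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.2.1, HTSeq 0.6.1 and DESeq2 were used. The genome build, the annotation and whether counting used strand are not given in the sources used here, so overlapping and antisense genes cannot be separated, and reads shared by near-identical copies in the 2 subgenomes may be split or lost.

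The deposited table gives for each library a whole-number read count per gene, which the authors did not normalise as far as the values show. The deposited FPKM values equal those counts divided by the exonic gene length and the library's total in 100% of values (tolerance 0.005). Each column name matched 1 sample. Of 82955 genes 61955 had a count. Totals ranged from 13072324 to 18788677, the 10 most abundant genes held 2.8 to 6.48% of a library, and within groups log-scale correlations across genes were 0.978 to 0.986. No replicate pair matched within sampling noise (chi-square per degree of freedom 2.08 to 8.56). Reads carry no molecular identifiers, so floors cover counting error only.

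Counts were tested with edgeR 4.0.16 in R 4.3.3 (read with the data.table package, version 1.17.8): TMM factors (0.804 to 1.11), 1 fit of all 30 libraries with a coefficient per group, estimateDisp (common biological coefficient of variation 0.0929), glmQLFit and glmQLFTest. The design fixed limma on log2(FPKM + 1) for a file without counts and edgeR for a file with counts, and the second applied. The 42311 genes with an FPKM of at least 1 in at least 3 libraries were tested, and these hold 99.57% of counts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1. The 17 comparisons were each salt time against 0 h in each cultivar, HY33 against HY9115 at each time, and the difference between the cultivars' changes from 0 h. A fold against a group with all libraries at 0 was computed against 3 counts over the group and is given as a lower bound.

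Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, and estimated) on log2 CPM with a prior count of 2, for lists of at least 5 tested members. The 37 lists, with tested members, were abscisic acid metabolism genes (18), abscisic acid signalling genes (76), proline genes (19), raffinose and trehalose genes (49), sodium and potassium transport genes (120), proton pump genes (84), calcium sensor genes (88), aquaporin genes (48), antioxidant genes (60), class III peroxidases (98), glutathione S-transferases (109), heat shock genes (117), AP2/ERF factors (99), WRKY factors (27), MYB factors (192), jasmonate genes (86), ethylene genes (43), auxin response genes (211), flavonoid and stilbene genes (63), lignin and phenylpropanoid genes (122), cell wall expansion genes (127), cellulose synthases (47), suberin, cutin and wax genes (87), sugar and starch genes (79), nitrogen assimilation genes (38), senescence genes (26), fermentation genes (28), pathogenesis-related genes (132), ribosomal protein genes (279), cell cycle and histone genes (118), clock genes (30), green shoot markers (40), root markers (31), cotyledon markers (38), nodule markers (58), rRNA-annotated models (139) and plastid-genome-type genes (13). Enrichment of GO and KEGG terms of 10 to 500 genes was tested one-sided by Fisher's exact test against the tested genes with a term, with 2106 terms per direction and comparison.

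The tests, comparisons, list themes, alternatives and naming rule were fixed before the data were examined. Because 0 genes have a text description, the lists were written as KO, GO and pathway identifiers after the annotation columns had been seen and before any test. Lists for LEA proteins and NAC factors were dropped, and the rRNA and plastid-genome-type lists were added as signs of RNA quality. Some list members do other work than the list's name says, such as 9-lipoxygenases in the jasmonate list and proline dehydrogenase, which degrades proline, in the proline list. A GO or KO annotation is present for 43336 genes, 27351 of them tested. Named genes are the 4 called genes per direction with the largest change against 0 h, or between cultivars or their changes, up to 3 called members per list, and the genes called between cultivars at all 5 times with the largest mean difference, with an FPKM of at least 5, no overlap between libraries for the first group, and an annotation. From these, genes were chosen for the text after their values were seen.

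The scripts were tested on simulated counts for 42311 genes with 100 genes changed at each of 2 sizes. For HY33 at 3 h against 0 h edgeR gave an adjusted p under the threshold to 86% of 2-fold changes (48% called) and 98% of 4-fold changes, with 6 unchanged genes called. For the difference in response at 3 h these were 74% (46% called) and 96%, with 5. A list built to change had a camera adjusted p of 1e-45 in the simulated HY33 comparison at 3 h.

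Alternatives were a stricter filter (FPKM 5) and none, quantile and TPM scaling, a fit of the compared libraries alone, robust estimation, no fold threshold, the replicate number as a block, leaving out each replicate in turn, and DESeq2 1.42.0. Added after seeing the data were scaling to total counts, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out the rRNA models or the genes of 4 chromosome stretches. The reference table of locus tags was not used here.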

Results

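Gene expression was measured by poly(A) RNA sequencing in whole seedlings of 2 peanut cultivars (Arachis hypogaea, an allotetraploid legume with 2 subgenomes). Per the labels, the cultivar HY33 tolerates salt and HY9115 is sensitive to it. Hydroponic seedlings at the 3-leaf stage were taken from water at 0 h or after 3, 12, 24 or 48 h in 100 mM NaCl, with 3 biological replicates in each of the 10 groups. The 30 libraries held 13072324 to 18788677 counts each, and 48854 to 51439 genes had a count in a library. Water was sampled only at 0 h, so salt, elapsed time and time of day were not separated. Nothing in the sources used here says whether the replicates came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical.

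Tests used 42311 genes. In what follows, a gene rose or fell where edgeR's quasi-likelihood test gave an adjusted p under 0.05 and a log2 change of at least 1, and list members not counted either way did not pass. Values are log2 changes ± SE or FPKM ± SD (n = 3). Of the 155 gene values named, the highest adjusted p among those called was 1.5e-07, and in 145 of the 145 that compare a pair of groups the libraries did not overlap, which is no test, since chance gives 10% for genes drawn at random and these were chosen for large changes. Library means of called lists did not overlap in 147 of 147 against 0 h and 63 of 67 between cultivars. Calling selects for this, so it is no test. The exceptions were cellulose synthases and clock genes at 12 h, class III peroxidases at 24 h and senescence genes at 48 h. List p-values come from camera with a preset correlation, and where no second p is given the call held with an estimated correlation. Coordinates are as deposited, on a genome build not given in the sources used here. Peanut genes often have near-identical copies in the other subgenome, so the split of counts within such a pair is uncertain.

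In 4 stretches of neighbouring genes HY33 at 0 h stood apart from HY9115 in all 3 libraries. The median log2 difference was -4.76 over 30 genes on chromosome 12 (117722663 to 118249169), -2.15 over 170 genes on chromosome 14 (137271521 to 140625566), 0.85 over 31 genes on chromosome 2 (100559158 to 102293503) and 0.78 over 185 genes on chromosome 4 (123083911 to 128569855). In HY33 at 3, 12, 24 and 48 h the chromosome 12 medians were -0.45, -0.14, -0.02 and -1.47. Later HY33 groups stood apart elsewhere too, with medians of -0.93 on chromosome 14 and 0.55 on chromosome 4 at 24 h, and of 0.38 and 0.64 on chromosome 2 at 3 and 48 h, while no HY9115 group mean lay beyond 0.1 in size. Counts of called genes that use HY33 are therefore also given without these 416 genes, none of which is named elsewhere in the report. The list and term tests kept these genes. Of the 19 proline genes 2 lay in the stretches, and no list had more than 5 members there. Whether enriched terms draw on the stretches was not tested.

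**Figure D1:**
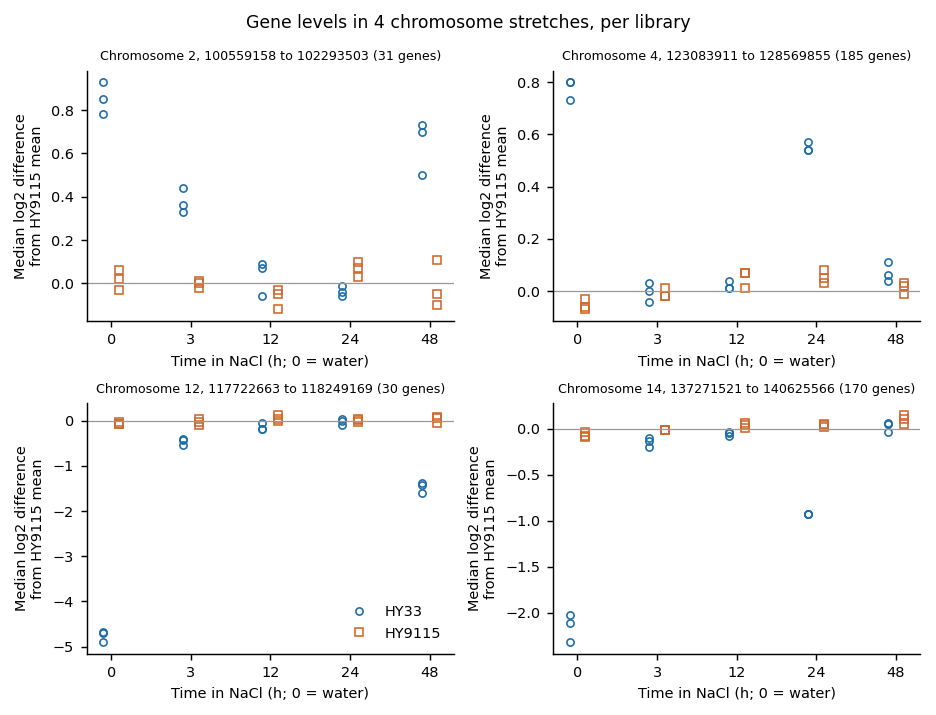
Median log2 difference of the genes in each of 4 chromosome stretches from their mean in the HY9115 libraries (y axis), in each of the 30 libraries (points), against time in NaCl in h, evenly spaced, with 0 the water samples (x axis). The HY33 libraries at 0 h lie between -4.9 and -4.68 on chromosome 12 and between -2.32 and -2.02 on chromosome 14.

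The first question was what changed within each cultivar in salt. After 3 h flavonoid, stilbene and jasmonate genes were high in HY33. Of the 63 flavonoid and stilbene genes 40 rose (adjusted p = 1.7e-25, and p = 0.12 with an estimated correlation), a list of enzymes that make phenolic pigments and defence compounds. Ah14g312300 (chromosome 14, 107662188 to 107667599), annotated both as a naringenin 3-dioxygenase and as a jasmonic acid hydrolase, rose by 4.83 ± 0.13 to 158 ± 1.54 against 5.47 ± 0.599 FPKM, and Ah04g265600, with the same annotation, rose by 4.52 ± 0.18. Of the 86 jasmonate genes 33 rose and 2 fell (adjusted p = 1.1e-14). They included the 13-lipoxygenase Ah13g069600 (3.31 ± 0.09), at the start of jasmonate synthesis, and the 9-lipoxygenase Ah09g111500 (2.85 ± 0.14), whose products are other oxylipins. Osmolyte genes that rose included the galactinol synthases Ah09g150200 (3.14 ± 0.09) and Ah16g113100 (3.81 ± 0.16), which supply raffinose synthesis, and the proline-making enzyme P5CS, Ah02g265800 (2.69 ± 0.08). Of the 49 raffinose and trehalose genes 15 rose and 1 fell (adjusted p = 0.00014, and p = 0.12 with an estimated correlation). The PP2C phosphatase Ah13g509400, a negative regulator of abscisic acid signalling, rose by 4.20 ± 0.13 and the invertase Ah18g025800, which splits sucrose, rose by 4.68 ± 0.15, while the SWEET sugar transporter Ah08g058900 fell by 5.31 ± 0.21.

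In HY33 at 3 h, of the 48 aquaporin genes 15 fell (adjusted p = 3.6e-06, and p = 0.17 with an estimated correlation), and of the 98 class III peroxidases 29 fell and 10 rose (adjusted p = 0.032, and p = 0.43 with an estimated correlation). Of the 127 cell wall expansion genes 33 fell and 12 rose (adjusted p = 0.001, and p = 0.12 with an estimated correlation). Examples were the plasma membrane water channels Ah13g039200 (-2.78 ± 0.12) and Ah10g152600 (-2.79 ± 0.11) and the pectinesterase Ah03g259400 (-3.39 ± 0.13). Of the 30 clock genes 15 rose and 4 fell (adjusted p = 1.8e-08, and p = 0.12 with an estimated correlation), with the morning gene LHY lower (Ah12g057500, -4.80 ± 0.09, and Ah02g050000, -4.67 ± 0.09) and PRR5 higher (Ah20g293500, 4.66 ± 0.16). The kinase gene Ah13g395100, annotated with the hyperosmotic salinity response, was at least 131-fold higher. Of the 40 green shoot markers 8 fell and 2 rose (adjusted p = 1.6e-08, and p = 0.2 with an estimated correlation). Of the 139 rRNA-annotated models, a list added as a sign of RNA quality, 65 fell and 1 rose (adjusted p = 5.1e-07, and p = 0.19 with an estimated correlation). Adjusted over the list alone, these counts were identical except for rRNA-annotated models (1 risen and 68 fallen). In total 5949 genes were called, 2795 higher and 3154 lower, and 5719 without the 4 stretches. TPM scaling turned the balance, with 3256 higher and 2688 lower, as did requiring an FPKM of 5 (1963 and 1945). camera called 19 of 37 lists, 1 with an estimated correlation.

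At 12 h in HY33 genes of heat shock proteins, which are chaperones, were high and cell division genes low. Of the 117 heat shock genes 69 rose and 1 fell (adjusted p = 7.4e-25), and the list held 1.28% ± 0.0361 of the counts against 0.473% ± 0.019 at 0 h. The small heat shock protein Ah09g260000 rose by 9.25 ± 0.29 to 114 ± 3.14 FPKM, and the HSP70 gene Ah19g016400 rose by 7.24 ± 0.26. Of the 118 cell cycle and histone genes 70 fell and 2 rose (adjusted p = 6.4e-16), with the histone H3 gene Ah10g252700 at -2.90 ± 0.20 and the cyclin A gene Ah08g131800 at -2.77 ± 0.26. Of the 87 suberin, cutin and wax genes 33 fell and 8 rose (adjusted p = 3e-04), a list of genes that build surface barriers. The fatty acyl reductase Ah18g072600 fell by 3.20 ± 0.21, while the peroxygenase Ah19g384500, annotated with seed maturation, rose by 3.06 ± 0.32. Among the 63 flavonoid and stilbene genes 49 rose and 1 fell (adjusted p = 1.8e-22, and p = 0.056 with an estimated correlation), among them Ah05g096400 (5.79 ± 0.40), annotated as leucoanthocyanidin reductase and as phenylcoumaran benzylic ether reductase. Of the 19 proline genes 8 rose and 1 fell (adjusted p = 0.0093, and p = 0.14 with an estimated correlation), among them P5CS Ah04g234400 (3.16 ± 0.08, 109 ± 4.28 against 13.1 ± 1.77 FPKM).

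Other large changes at 12 h in HY33 included the plasma membrane proton pumps Ah20g424100 (3.58 ± 0.10) and Ah10g333500 (4.41 ± 0.16), the tonoplast-type aquaporin Ah05g283400 (7.17 ± 0.27) and the auxin-conjugating GH3 enzyme Ah01g129300 (7.98 ± 0.21). The peroxidase Ah11g493600 was at least 211-fold lower, and the pectin-cutting polygalacturonase Ah15g483500 fell by 7.62 ± 0.25. Among the 49 raffinose and trehalose genes 19 rose and 3 fell (adjusted p = 1.4e-05), and of the 98 class III peroxidases 48 fell and 19 rose (adjusted p = 0.017, and p = 0.4 with an estimated correlation). Tissue markers moved too: of the 40 green shoot markers 31 fell (adjusted p = 1.2e-18, and p = 0.056 with an estimated correlation), and of the 38 cotyledon markers 23 rose (adjusted p = 2.4e-08). Models of rRNA held 0.0514% ± 0.00467 of the counts against 0.0556% ± 0.0057 at 0 h. The counts adjusted over the list alone were identical. The test called 10130 genes (4670 higher, 5460 lower), 9853 without the 4 stretches, and camera 19 lists, 5 with an estimated correlation. Requiring an FPKM of 5 turned the balance (3162 and 3110). Scaling to total counts moved the median of all genes by -0.101 log2.

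At 24 h in HY33 genes of chaperones and of glutathione S-transferases, which attach glutathione to reactive compounds, were high. Of the 109 glutathione S-transferases 45 rose and 7 fell (adjusted p = 1.9e-09, and p = 0.23 with an estimated correlation), and the list took 1.3% ± 0.0208 of all counts against 0.362% ± 0.0286 at 0 h. Ah01g069800 rose by 7.47 ± 0.17 and the abundant Ah20g111800 rose by 3.04 ± 0.13 to 3670 ± 44.9 against 486 ± 49.5 FPKM. Among the 117 heat shock genes 70 rose and 1 fell (adjusted p = 2.8e-24), and of the 63 flavonoid and stilbene genes 46 rose and 1 fell (adjusted p = 7e-23, and p = 0.07 with an estimated correlation). The small heat shock protein Ah02g273600 rose by 7.45 ± 0.21. The ACC synthase Ah04g364100 and the ACC oxidase Ah17g079400, enzymes of ethylene synthesis, rose by 5.40 ± 0.38 and 5.24 ± 0.26, while the list of 43 ethylene genes did not pass (10 rose and 5 fell, adjusted p = 0.14). Asparagine synthase Ah01g053200 rose by 3.67 ± 0.08. Among the 118 cell cycle and histone genes 66 fell and 3 rose (adjusted p = 1.1e-17), and of the 87 suberin, cutin and wax genes 35 fell and 7 rose (adjusted p = 0.00011). Of the 98 class III peroxidases 44 fell and 18 rose (adjusted p = 0.018, and p = 0.38 with an estimated correlation). The histone H3 gene Ah20g394200 fell by 3.72 ± 0.29. The nicotianamine synthase Ah18g247900, which makes a metal chelator, fell by 6.31 ± 0.33, and Ah08g038200, annotated as fraxetin 5-hydroxylase of coumarin synthesis, fell by 9.25 ± 0.31. The nitrate transporter Ah03g015200 of the NRT2 family fell by 4.04 ± 0.22, and the SWEET transporter Ah17g416500 fell by 5.42 ± 0.17.

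Among tissue markers in HY33 at 24 h, of the 31 root markers 17 fell and 1 rose (adjusted p = 0.00088, and p = 0.07 with an estimated correlation), and of the 38 cotyledon markers 17 rose (adjusted p = 0.00038, and p = 0.11 with an estimated correlation). Among the 40 green shoot markers 12 fell (adjusted p = 3e-10, and p = 0.18 with an estimated correlation), where the RuBisCO small subunit gene Ah10g374400 fell by 1.62 ± 0.08. Of the 139 rRNA-annotated models 74 fell and 1 rose (adjusted p = 2.7e-05, and p = 0.25 with an estimated correlation). These list counts stayed as given when adjusted over the list alone except for class III peroxidases (18 risen and 45 fallen), cotyledon markers (18 risen) and rRNA-annotated models (1 risen and 76 fallen). Called genes numbered 10038, with 4385 higher and 5653 lower, and 9837 without the 4 stretches. camera called 17 lists, 3 with an estimated correlation, and the median of all genes moved by -0.149 log2 with TPM scaling and -0.121 with total counts.

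At 48 h in HY33 green shoot and surface barrier genes were low. Among 40 green shoot markers 30 fell (adjusted p = 1e-15, and p = 0.065 with an estimated correlation), and the RuBisCO small subunit Ah10g374400, of the carbon-fixing enzyme, fell by 3.38 ± 0.09 to 722 ± 32.6 against 9770 ± 308 FPKM. Among the 87 suberin, cutin and wax genes 53 fell and 7 rose (adjusted p = 2.6e-06), and of the 47 cellulose synthases 26 fell and 2 rose (adjusted p = 4.6e-07, and p = 0.062 with an estimated correlation). The fatty acyl reductase Ah16g468600 fell by 4.14 ± 0.24, the feruloyl transferase Ah18g469000 fell by 4.38 ± 0.28 and the cellulose synthase Ah04g142000 fell by 2.51 ± 0.19. Among 63 flavonoid and stilbene genes 51 rose and 2 fell (adjusted p = 3.1e-20, and p = 0.062 with an estimated correlation), and of the 109 glutathione S-transferases 59 rose and 9 fell (adjusted p = 1.7e-10, and p = 0.19 with an estimated correlation). Flavonoid and stilbene genes held 0.872% ± 0.0516 of the counts against 0.0754% ± 0.00596 at 0 h. Ah17g434000, annotated with chalcone synthase activity, was at least 1520-fold higher, the methyltransferase Ah20g521200 of lignin synthesis rose by 7.65 ± 0.28, and glutathione S-transferase Ah20g111800 rose by 4.49 ± 0.14 to 8410 ± 446 against 486 ± 49.5 FPKM. The citrate and iron transporter Ah08g298300 was at least 1280-fold lower and the fraxetin 5-hydroxylase Ah08g038200 at least 932-fold lower. The amino acid transporter Ah08g077400 was at least 433-fold higher, and the oxophytodienoate reductase Ah15g153900, of the jasmonate pathway, rose by 7.39 ± 0.19. Cyclin B gene Ah20g009600, needed for mitosis, fell by 4.78 ± 0.23.

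In HY33 at 48 h, of the 211 auxin response genes 86 fell and 12 rose (adjusted p = 2.1e-05), and of the 117 heat shock genes 66 rose and 5 fell (adjusted p = 8.8e-16). Of the 48 aquaporin genes 26 fell and 4 rose (adjusted p = 1.6e-06, and p = 0.13 with an estimated correlation), and of the 127 cell wall expansion genes 72 fell and 22 rose (adjusted p = 0.00035, and p = 0.062 with an estimated correlation). Among 118 cell cycle and histone genes 66 fell and 2 rose (adjusted p = 1.7e-10, and p = 0.062 with an estimated correlation), and of the 279 ribosomal protein genes 35 rose and 9 fell (adjusted p = 1.7e-10, and p = 0.43 with an estimated correlation). Of the 122 lignin and phenylpropanoid genes 45 rose and 36 fell (adjusted p = 0.039, and p = 0.43 with an estimated correlation). Their median of 0.26 turned to -0.22 with TPM scaling (37 rose and 48 fell) and -0.11 with total counts (39 and 46). Of the 84 proton pump genes 7 rose and 7 fell (adjusted p = 0.0015, and p = 0.062 with an estimated correlation), with a median of 0.45 that turned to -0.04 with TPM scaling. Of the 43 ethylene genes 11 rose and 5 fell (adjusted p = 0.027, and p = 0.42 with an estimated correlation), with a median of 0.37 that turned to -0.12. Of the 31 root markers 15 fell and 1 rose (adjusted p = 0.0021, and p = 0.062 with an estimated correlation), and of the 38 cotyledon markers 18 rose and 1 fell (adjusted p = 0.0022, and p = 0.13 with an estimated correlation). Among the 139 rRNA-annotated models 59 fell and 1 rose (adjusted p = 0.0024, and p = 0.43 with an estimated correlation). When adjusted over the list alone, the counts did not move except for auxin genes (12 risen and 85 fallen) and rRNA-annotated models (1 risen and 56 fallen). edgeR called 14558 genes, 6067 higher and 8491 lower, and 14300 without the 4 stretches. With TPM scaling 3821 were higher and 13144 lower, the median of all genes moving by -0.49 log2, and with total counts 4201 and 11842 (-0.376). camera called 19 lists, 3 with an estimated correlation.

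**Figure D2:**
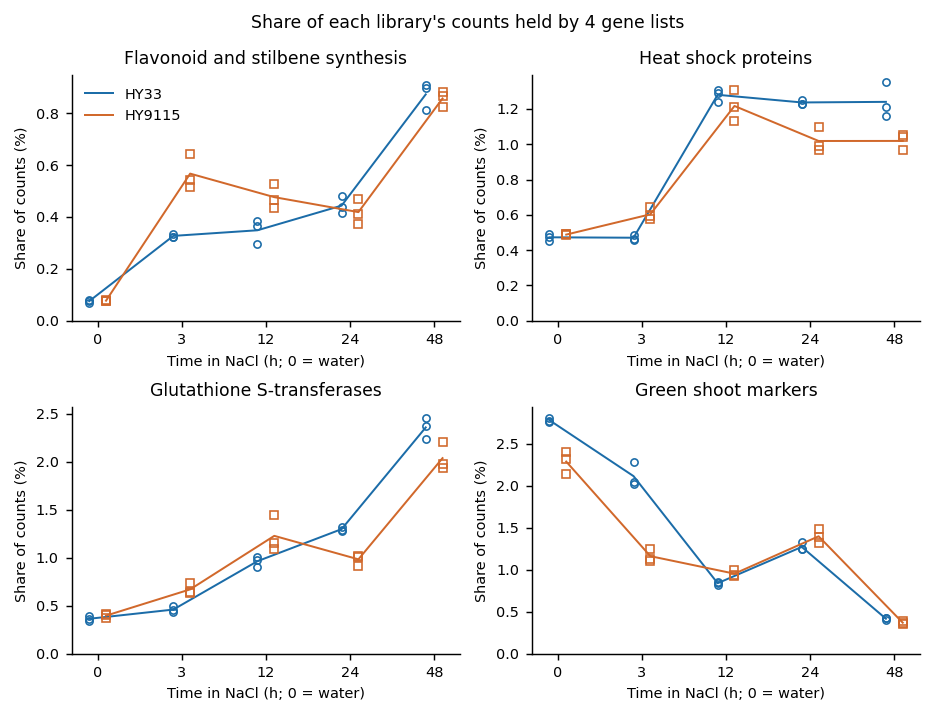
Share of each library's counts (y axis, percent) held by flavonoid and stilbene, heat shock and glutathione S-transferase genes and by green shoot markers, against time in NaCl in h, evenly spaced, with 0 the water samples (x axis). Points are libraries, lines join the means of 3, and the green shoot share is 2.78% at 0 h and 0.415% at 48 h in HY33, and 2.29% and 0.367% in HY9115.

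In HY9115 at 3 h flavonoid, stilbene and chaperone genes were high. Of the 63 flavonoid and stilbene genes 51 rose (adjusted p = 1.1e-37), and the list took 0.567% ± 0.0673 of the counts against 0.0773% ± 0.0024 at 0 h. Ah14g312300 rose by 5.89 ± 0.14 to 195 ± 12.6 against 3.34 ± 1.06 FPKM, and the chalcone synthase type gene Ah14g026500 rose by 6.37 ± 0.24. Among 117 heat shock genes 46 rose and 3 fell (adjusted p = 1.5e-12), including the HSP70 gene Ah01g318500 (5.19 ± 0.28), the small heat shock protein Ah09g260000 (7.24 ± 0.39) and the heat shock factor Ah09g358500 (5.70 ± 0.28). Among 49 raffinose and trehalose genes 22 rose (adjusted p = 5.5e-08), and of the 86 jasmonate genes 39 rose and 2 fell (adjusted p = 2.8e-15). The galactinol synthase Ah19g203200 stood at 5.04 ± 0.22 and the 9-lipoxygenase Ah09g111500 at 4.30 ± 0.15. Among the 109 glutathione S-transferases 36 rose (adjusted p = 3e-06, and p = 0.3 with an estimated correlation), and of the 122 lignin and phenylpropanoid genes 32 rose and 8 fell (adjusted p = 0.0014, and p = 0.23 with an estimated correlation). Ferulate 5-hydroxylase Ah11g098200 rose by 5.52 ± 0.25. The PP2C gene Ah13g509400 rose by 4.39 ± 0.13, the invertase Ah08g142600 rose by 5.24 ± 0.15 and the clock gene GIGANTEA, Ah15g560100, rose by 4.92 ± 0.11. The chaperone gene Ah08g319800 was at least 77.2-fold higher, neomenthol dehydrogenase Ah08g000100 fell by 5.47 ± 0.21 and the wax gene Ah06g355300 fell by 4.69 ± 0.31.

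In HY9115 at 3 h, of the 127 cell wall expansion genes 44 fell and 15 rose (adjusted p = 9.4e-05, and p = 0.055 with an estimated correlation), and of the 48 aquaporin genes 15 fell and 4 rose (adjusted p = 2.3e-06, and p = 0.13 with an estimated correlation). Among the 98 class III peroxidases 31 fell and 7 rose (adjusted p = 0.022, and p = 0.36 with an estimated correlation), and of the 87 suberin, cutin and wax genes 13 fell and 6 rose (adjusted p = 0.023). Polygalacturonase Ah15g483500 stood at -4.20 ± 0.15. Of the 132 pathogenesis-related genes 38 rose and 7 fell (adjusted p = 0.0015, and p = 0.06 with an estimated correlation), and of the 30 clock genes 12 rose and 4 fell (adjusted p = 2.1e-07, and p = 0.1 with an estimated correlation). Among tissue markers, of the 40 green shoot markers 14 fell (adjusted p = 8.1e-18, and p = 0.06 with an estimated correlation), and of the 38 cotyledon markers 17 rose (adjusted p = 0.005, and p = 0.15 with an estimated correlation). Adjusted over the list alone, these counts were identical except for cell wall genes (16 risen and 45 fallen). There were 6221 called genes, 3500 higher and 2721 lower, and 20 called lists, 5 with an estimated correlation.

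HY9115 at 12 h held more chaperone and flavonoid transcript. Of the 117 heat shock genes 67 rose and 2 fell (adjusted p = 2.7e-23), with the small heat shock proteins Ah09g260000 at 8.49 ± 0.34 and Ah19g329300 at 8.01 ± 0.33. Among the 63 flavonoid and stilbene genes 51 rose and 2 fell (adjusted p = 2.7e-26), and of the 109 glutathione S-transferases 40 rose and 4 fell (adjusted p = 3.2e-08, and p = 0.24 with an estimated correlation). The glutathione S-transferase Ah13g246900 rose by 8.06 ± 0.23 to 73.6 ± 8.51 against 0.287 ± 0.0451 FPKM. Of the 118 cell cycle and histone genes 65 fell and 1 rose (adjusted p = 4.2e-12, and p = 0.053 with an estimated correlation), and of the 47 cellulose synthases 14 fell (adjusted p = 9.4e-06, and p = 0.092 with an estimated correlation). The histone H2B gene Ah19g415300 stood at -3.03 ± 0.32 and the cellulose synthase Ah16g479800 at -2.53 ± 0.17. Among the 127 cell wall expansion genes 57 fell and 21 rose (adjusted p = 0.001, and p = 0.089 with an estimated correlation), and polygalacturonase Ah15g483500 fell by 9.39 ± 0.25 to 0.0933 ± 0.0551 against 68.4 ± 10.5 FPKM. A potassium transporter of the KUP family, Ah12g423500, rose by 3.31 ± 0.16, the proton pump Ah20g424100 rose by 3.34 ± 0.09 and the galactinol synthase Ah19g203200 rose by 5.62 ± 0.21. The nitrate transporter Ah03g015200 fell by 4.83 ± 0.21, and the abscisic acid receptor type gene Ah04g278900 fell by 5.54 ± 0.40.

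Among 139 rRNA-annotated models 128 rose (adjusted p = 3e-19) in HY9115 at 12 h, with 0.118% ± 0.05 of the counts against 0.0126% ± 0.0015 at 0 h and single libraries between 0.0848% and 0.175%. Among 87 suberin, cutin and wax genes 29 fell and 9 rose (adjusted p = 0.0011), and of the 19 proline genes 8 rose and 2 fell (adjusted p = 0.015, and p = 0.14 with an estimated correlation). Of the 49 raffinose and trehalose genes 19 rose and 3 fell (adjusted p = 0.00019, and p = 0.075 with an estimated correlation). Among tissue markers, of the 40 green shoot markers 22 fell (adjusted p = 4.4e-15, and p = 0.084 with an estimated correlation), and of the 31 root markers 13 fell (adjusted p = 0.0018, and p = 0.067 with an estimated correlation). Of the 38 cotyledon markers 21 rose and 1 fell (adjusted p = 9.2e-07). The counts adjusted over the list alone were identical except for rRNA-annotated models (130 risen). The test called 10067 genes, 4835 higher and 5232 lower. With TPM scaling 4083 were higher and 6759 lower, and the median of all genes moved by -0.18 log2 (-0.118 with total counts). The balance turned when an FPKM of 5 was required (3243 and 2986) and was near even with no filter (5891 and 5884). camera called 18 lists, 5 with an estimated correlation.

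At 24 h HY9115 aquaporins were low and flavonoid and chaperone genes high. Among the 48 aquaporin genes 25 fell and 4 rose (adjusted p = 6e-11), the tonoplast type gene Ah20g381000 falling to 3.69 ± 0.588 against 47.9 ± 5.78 FPKM (log2 -3.64 ± 0.13), although another, Ah05g283400, rose by 4.71 ± 0.24. Among 63 flavonoid and stilbene genes 48 rose and 2 fell (adjusted p = 1.5e-24), and of the 117 heat shock genes 62 rose and 2 fell (adjusted p = 4.4e-20). The chalcone synthase type gene Ah14g026600 stood at 4.60 ± 0.16 and the small heat shock protein Ah02g273600 at 7.25 ± 0.22. Among 127 cell wall expansion genes 56 fell and 16 rose (adjusted p = 8.2e-06), and of the 118 cell cycle and histone genes 62 fell and 1 rose (adjusted p = 1.1e-15). Among 98 class III peroxidases 47 fell and 12 rose (adjusted p = 1e-05, and p = 0.12 with an estimated correlation). The histone H2A gene Ah16g037700 fell by 2.80 ± 0.13, and polygalacturonase Ah05g308500 fell by 9.62 ± 0.33. Alcohol dehydrogenase Ah10g258500, a fermentation enzyme, fell by 4.76 ± 0.18, while Ah18g029900 of the same family rose by 1.81 ± 0.11. The ACC oxidase Ah17g079400 rose by 4.14 ± 0.26 and GIGANTEA Ah05g462700 rose by 4.04 ± 0.10.

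Among markers in HY9115 at 24 h, of the 31 root markers 14 fell (adjusted p = 0.00034), and of the 38 cotyledon markers 21 rose and 3 fell (adjusted p = 4.7e-05). Of the 40 green shoot markers 5 fell (adjusted p = 1.2e-07, and p = 0.28 with an estimated correlation), and of the 139 rRNA-annotated models 22 rose (adjusted p = 0.044, and p = 0.6 with an estimated correlation). Among 109 glutathione S-transferases 43 rose and 7 fell (adjusted p = 1.2e-06, and p = 0.36 with an estimated correlation), and of the 87 suberin, cutin and wax genes 23 fell and 5 rose (adjusted p = 0.013). Among the 30 clock genes 13 rose and 2 fell (adjusted p = 6.1e-10, and p = 0.052 with an estimated correlation). These list counts stayed as given when adjusted over the list alone except for rRNA-annotated models (9 risen). A total of 8346 genes were called, 3891 higher and 4455 lower, a balance that turned when an FPKM of 5 was required (2621 and 2426) and with no fold threshold (11669 and 10652). camera called 17 lists, 8 with an estimated correlation.

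In HY9115 at 48 h surface barrier and aquaporin genes were low. Of the 87 suberin, cutin and wax genes 52 fell and 9 rose (adjusted p = 2.8e-06), and of the 48 aquaporin genes 33 fell and 4 rose (adjusted p = 6.6e-09, and p = 0.081 with an estimated correlation). Of the 47 cellulose synthases 32 fell and 3 rose (adjusted p = 1.2e-07, and p = 0.08 with an estimated correlation). The CER1-type wax gene Ah16g443500 was at least 152-fold lower, the aquaporin Ah10g296700 fell by 5.57 ± 0.37 and the cellulose synthase Ah04g142000 fell by 3.39 ± 0.21. Among the 40 green shoot markers 30 fell (adjusted p = 4.8e-14, and p = 0.082 with an estimated correlation), RuBisCO small subunit Ah10g374400 falling to 635 ± 40 against 6730 ± 274 FPKM (log2 -3.15 ± 0.09). Polygalacturonase Ah15g483500 was at least 1820-fold lower, the zinc transporter Ah08g161200 at least 639-fold lower and the oxidosqualene cyclase Ah15g478400, of triterpene synthesis, at least 304-fold lower. Of the 63 flavonoid and stilbene genes 49 rose and 4 fell (adjusted p = 2.4e-18, and p = 0.081 with an estimated correlation), and of the 117 heat shock genes 69 rose and 6 fell (adjusted p = 1.9e-14). Of the 109 glutathione S-transferases 52 rose and 11 fell (adjusted p = 1e-07, and p = 0.25 with an estimated correlation). The chalcone synthase type gene Ah04g017300 rose by 5.76 ± 0.14 to 599 ± 11.7 against 13.2 ± 1.1 FPKM, HSP70 gene Ah01g318500 rose by 7.77 ± 0.27 and glutathione S-transferase Ah01g069800 rose by 8.27 ± 0.17. Among the 43 ethylene genes 14 rose and 7 fell (adjusted p = 0.0033, and p = 0.22 with an estimated correlation), with ACC synthase Ah04g364100 at 8.02 ± 0.39. The oxophytodienoate reductase Ah05g191500 was at least 118-fold higher, PP2C Ah13g509400 rose by 6.41 ± 0.12, and the raffinose synthase Ah13g315800 rose by 6.77 ± 0.21.

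In HY9115 at 48 h, of the 98 class III peroxidases 57 fell and 18 rose (adjusted p = 0.00063, and p = 0.22 with an estimated correlation), and of the 211 auxin response genes 86 fell and 16 rose (adjusted p = 0.00063, and p = 0.081 with an estimated correlation). Among the 118 cell cycle and histone genes 67 fell and 4 rose (adjusted p = 1.3e-08, and p = 0.082 with an estimated correlation), and of the 127 cell wall expansion genes 72 fell and 24 rose (adjusted p = 7.3e-05, and p = 0.075 with an estimated correlation). The peroxidase Ah01g293200 was at least 333-fold lower and Ah11g034000 at least 138-fold higher. Among the 31 root markers 20 fell and 2 rose (adjusted p = 0.00015), and of the 38 cotyledon markers 22 rose and 4 fell (adjusted p = 0.00034, and p = 0.081 with an estimated correlation). Of the 139 rRNA-annotated models 42 rose (adjusted p = 0.0085, and p = 0.57 with an estimated correlation). When adjusted over the list alone, the counts did not move except for rRNA-annotated models (26 risen). Calls numbered 15123, 6115 higher and 9008 lower, and TPM scaling gave 4563 and 11661, with the median of all genes moved by -0.335 log2 (-0.26 with total counts). camera called 18 lists, 3 with an estimated correlation.

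**Figure D3:**
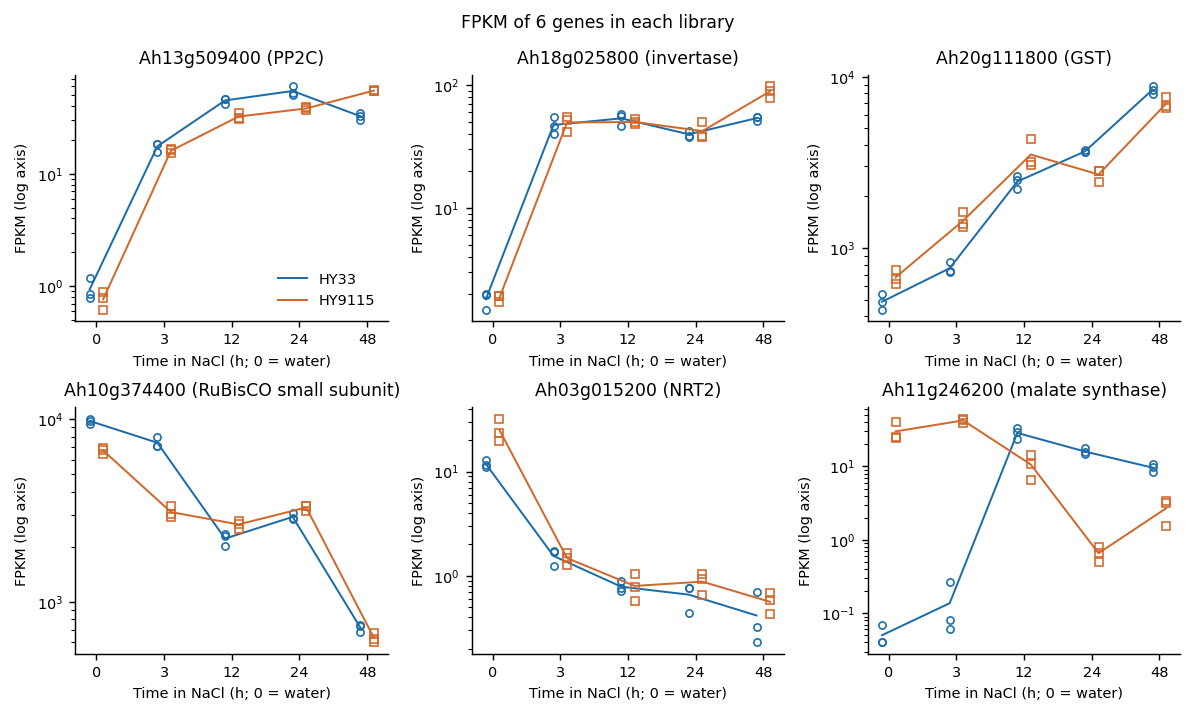
FPKM (y axis, log scale) of 6 genes in each of the 30 libraries (points) against time in NaCl in h, evenly spaced, with 0 the water samples (x axis); lines join the means of 3 libraries. The PP2C and invertase genes are higher at every salt time than at 0 h in both cultivars, while the malate synthase gene lies at 0.05 ± 0.0173 FPKM at 0 h, 28.7 ± 4.89 at 12 h and 9.62 ± 1.11 at 48 h in HY33 and at 30.1 ± 8.82, 10.6 ± 3.98 and 2.69 ± 0.988 in HY9115, where the 3 h value is 42.5 ± 2.72 and the 24 h value 0.657 ± 0.155.

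The next question was how far the cultivars shared these changes. PP2C Ah13g509400 and invertase Ah18g025800 were among the genes that rose in both cultivars at each time, and nitrate transporter Ah03g015200 among those that fell. Genes that rose in both numbered 1925, 3550, 3087 and 4565 at 3, 12, 24 and 48 h, against 231, 534, 403 and 877 from independent lists of those sizes, and genes that fell in both 1846, 3710, 3621 and 6931, against 203, 675, 595 and 1808. The same-direction genes made up 45.2, 56.4, 57.8 and 63.6% of those called in either cultivar, and 53, 73, 65 and 109 genes moved in opposite directions. Without the 4 stretches 1899, 3497, 3038 and 4507 rose in both and 1825, 3673, 3595 and 6880 fell in both. No library enters both cultivars' comparisons.

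At all 4 salt times 1298 genes rose and 1346 fell in HY33, against 4.58 and 10.9 from independent lists (1191 and 1319 without the 4 stretches), and 1959 rose and 1220 fell in HY9115, against 5.32 and 7.54. Those comparisons share their 0 h libraries. In 5 simulations per cultivar with no effect edgeR called 0 genes at all 4 times. With an unadjusted p under 0.05 at all 4 times, 40 to 50 genes were higher and 22 to 36 lower in HY33, and 37 to 59 and 20 to 30 in HY9115. The 3 controls were not split, since a part would keep fewer than 2 libraries, and part of the excess may come from the shared controls.

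The next comparisons ask where HY33 differed from HY9115 at each time, with higher and lower meant of HY33. In water at 0 h the Rac-type GTPase gene Ah11g250800 was at least 415-fold higher (27.4 ± 4.77 FPKM in HY33) and the calcium-transporter type ATPase Ah19g322700 at least 277-fold higher, while Ah20g199900, annotated with GTPase activity and microtubule binding, was at least 335-fold lower and the beta-glucosidase Ah10g229000 at least 282-fold lower. Ah01g165300, annotated with the response to starvation, was higher by 9.50 ± 0.27. Malate synthase Ah11g246200, of the glyoxylate cycle that turns fat into sugar, stood at 0.05 ± 0.0173 FPKM in HY33 and 30.1 ± 8.82 in HY9115, and glyoxylate cycle genes were enriched among those lower in HY33 (13 of 25, adjusted p = 2e-11). Of the 211 auxin response genes 21 were higher and 3 were lower (adjusted p = 0.00015, and p = 0.059 with an estimated correlation), and of the 38 nitrogen assimilation genes 7 were lower and 2 were higher (adjusted p = 2.8e-05). Among the 19 proline genes 1 was lower (adjusted p = 0.00015). Among the 139 rRNA-annotated models 106 were higher and 1 was lower (adjusted p = 1.1e-32), and the 40 green shoot markers had a median difference of 0.20 log2 (adjusted p = 0.00015, and p = 0.51 with an estimated correlation), with 2.78% ± 0.0265 of the counts in HY33 and 2.29% ± 0.133 in HY9115. Adjusted over the list alone, these counts were identical except for rRNA-annotated models (111 higher and 1 lower). edgeR called 2417 genes, 1255 higher and 1162 lower, of which 249 lay in the 4 stretches (2168 without them). The balance turned with TPM scaling (1082 and 1299), limma on log2(FPKM + 1) (687 and 736) and without the rRNA models (1149 and 1161), and was even when an FPKM of 5 was required (672 and 672) and with limma on log2(FPKM + 0.1) (1146 and 1146). camera called 10 lists, 3 with an estimated correlation.

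At 3 h in salt HY33 held less chaperone, flavonoid and cotyledon marker transcript than HY9115. Among the 117 heat shock genes 34 were lower and 1 was higher (adjusted p = 4.5e-18), and of the 63 flavonoid and stilbene genes 16 were lower and 1 was higher (adjusted p = 5.7e-22, and p = 0.05 with an estimated correlation). Among the 109 glutathione S-transferases 10 were lower (adjusted p = 2.3e-10, and p = 0.24 with an estimated correlation), and of the 38 cotyledon markers 14 were lower (adjusted p = 5.4e-09). Flavonoid and stilbene genes held 0.327% ± 0.00794 of the counts in HY33 and 0.567% ± 0.0673 in HY9115, and the small heat shock protein Ah09g260000 stood at 0.0667 ± 0.0702 and 17.5 ± 6 FPKM. The phosphatase gene Ah02g127400 was at least 386-fold higher, Ah15g316900, annotated with Golgi transport, at least 386-fold higher, and the auxin efflux carrier Ah18g312700 at least 237-fold lower. Among 40 green shoot markers 4 were higher and 1 was lower (adjusted p = 1.3e-22), and of the 211 auxin response genes 8 were higher and 5 were lower (adjusted p = 4e-05). Of the 28 fermentation genes 5 were lower and 1 was higher (adjusted p = 0.00023), and of the 139 rRNA-annotated models 33 were higher (adjusted p = 3.3e-08, and p = 0.19 with an estimated correlation). Of the 13 plastid-genome-type genes 5 were higher (adjusted p = 0.0035, and p = 0.24 with an estimated correlation). The counts adjusted over the list alone were identical except for heat shock proteins (1 higher and 35 lower), flavonoid and stilbene genes (1 higher and 17 lower) and auxin genes (9 higher and 5 lower). The test called 2474 genes, 873 higher and 1601 lower (2429 without the 4 stretches), and camera 14 lists, 6 with an estimated correlation.

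At 12 h the calcium-transporter type ATPase Ah19g322700 was at least 166-fold higher in HY33 and Ah15g316900 at least 250-fold higher, and the homogentisate phytyltransferase Ah11g190300, of vitamin E synthesis, was at least 153-fold lower, as was the nucleocytoplasmic transport gene Ah05g073400 (at least 173-fold). Among 63 flavonoid and stilbene genes 9 were lower and 2 were higher (adjusted p = 3.1e-10, and p = 0.26 with an estimated correlation), and of the 127 cell wall expansion genes 10 were higher and 2 were lower (adjusted p = 0.0067, and p = 0.25 with an estimated correlation). Of the 18 abscisic acid metabolism genes 4 were higher (adjusted p = 0.0047, and p = 0.15 with an estimated correlation), and of the 139 rRNA-annotated models 44 were lower and 1 was higher (adjusted p = 3.1e-10, and p = 0.18 with an estimated correlation). Among 13 plastid-genome-type genes 1 was lower (adjusted p = 0.0033, and p = 0.26 with an estimated correlation). These list counts stayed as given when adjusted over the list alone except for cell wall genes (10 higher and 3 lower) and rRNA-annotated models (1 higher and 51 lower). Calls numbered 1590, 827 higher and 763 lower (1560 without the 4 stretches), a balance that turned with no fold threshold (3047 and 3147). camera called 13 lists, with 0.15 the lowest adjusted p from an estimated correlation.

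At 24 h HY33 stood above HY9115 in some chaperone and transcription factor genes: of the 117 heat shock genes 10 were higher and 3 were lower (adjusted p = 2.6e-08, and p = 0.1 with an estimated correlation), and of the 99 AP2/ERF factors 11 were higher and 1 was lower (adjusted p = 0.00091, and p = 0.069 with an estimated correlation), the second list acting in stress and ethylene responses. Of the 98 class III peroxidases 11 were higher and 1 was lower (adjusted p = 0.0098, and p = 0.52 with an estimated correlation), a list whose median turned from 0.08 to -0.05 with TPM scaling (7 higher, 1 lower). Of the 88 calcium sensor genes 2 were higher (adjusted p = 0.023, and p = 0.26 with an estimated correlation), and of the 60 antioxidant genes 2 were higher (adjusted p = 0.049, and p = 0.52 with an estimated correlation). Their medians turned to -0.06 and -0.04 with TPM scaling. Genes higher in HY9115 were enriched for diterpenoid synthesis (15 of 30, adjusted p = 7.9e-14), a branch of terpene metabolism. Ah19g322700 was at least 175-fold higher in HY33, and Ah11g190300 at least 254-fold and Ah18g312700 at least 235-fold lower. Among 139 rRNA-annotated models 10 were higher (adjusted p = 0.025, and p = 0.58 with an estimated correlation). When adjusted over the list alone, the counts did not move except for rRNA-annotated models (2 higher). There were 2182 calls, 1019 higher and 1163 lower, of which 110 lay in the 4 stretches (2072 without them). TPM scaling gave 740 and 1744 and moved the median of all genes by -0.168 log2, and quantile scaling gave 1114 and 1083. camera called 13 lists, and 0.069 was the lowest adjusted p with an estimated correlation.

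At 48 h HY33 held more peroxidase and cell wall transcript than HY9115. Among the 98 class III peroxidases 36 were higher and 5 were lower (adjusted p = 0.00026, and p = 0.21 with an estimated correlation), and of the 127 cell wall expansion genes 27 were higher and 1 was lower (adjusted p = 0.00011, and p = 0.15 with an estimated correlation). Among the 87 suberin, cutin and wax genes 17 were higher and 1 was lower (adjusted p = 0.047, and p = 0.15 with an estimated correlation), and of the 132 pathogenesis-related genes 22 were higher and 2 were lower (adjusted p = 0.0088, and p = 0.18 with an estimated correlation). Genes higher in HY33 were enriched for lactoperoxidase activity (39 of 113, adjusted p = 5.2e-17). Among the 38 cotyledon markers 10 were lower (adjusted p = 0.0088, and p = 0.2 with an estimated correlation), and of the 40 green shoot markers 1 was higher (adjusted p = 0.016, and p = 0.58 with an estimated correlation). Among the 28 fermentation genes 8 were higher and 1 was lower (adjusted p = 0.016, and p = 0.18 with an estimated correlation). Among 118 cell cycle and histone genes 13 were higher (adjusted p = 0.016, and p = 0.47 with an estimated correlation), with a median of 0.19 that turned to -0.05 with TPM scaling (6 higher, 4 lower). The glucuronoxylan methyltransferase Ah03g599500, which modifies secondary walls, was at least 470-fold lower, the ribosomal protein type gene Ah04g101100 at least 283-fold lower and the amidohydrolase Ah18g314200 at least 162-fold higher. Adjusted over the list alone, these counts were identical. The 3818 calls (3736 without the 4 stretches) split into 2525 higher and 1293 lower, into 1686 and 2272 with TPM scaling (median of all genes moved by -0.234 log2) and into 2005 and 1714 with total counts (-0.127). camera called 17 lists, and the lowest adjusted p with an estimated correlation was 0.15. At all 5 times 257 genes were higher in HY33 and 211 lower (256 and 197 without the 4 stretches), against 0.000727 and 0.000666 from independent lists.

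The last comparisons test whether the change from 0 h itself differed between cultivars, with higher where it was larger, or less negative, in HY33. At 3 h chaperone and flavonoid genes had the lower response in HY33: of the 117 heat shock genes 32 were lower and 2 were higher (adjusted p = 3.7e-16), and of the 63 flavonoid and stilbene genes 20 were lower (adjusted p = 7e-20, and p = 0.11 with an estimated correlation). The glutathione S-transferase Ah13g246900 differed by -7.16 ± 0.84 and the beta-galactosidase Ah06g251100 by -7.14 ± 0.31. The latter went from 27.5 ± 2.75 to 30.2 ± 4.52 FPKM in HY33 and from 0.113 ± 0.133 to 18.4 ± 1.28 in HY9115. The starch phosphorylase type gene Ah06g434000 differed by 6.95 ± 0.41, going from 0.0333 ± 0.0577 to 5.7 ± 0.987 FPKM in HY33 and from 8.46 ± 0.69 to 10.4 ± 0.278 in HY9115. Among 38 cotyledon markers 11 were lower and 1 was higher (adjusted p = 7.6e-06, and p = 0.088 with an estimated correlation), and of the 139 rRNA-annotated models 38 were lower and 1 was higher (adjusted p = 3.2e-12, and p = 0.11 with an estimated correlation), while the 40 green shoot markers had a median difference of 0.34 log2 (adjusted p = 1.7e-10, and p = 0.21 with an estimated correlation). The counts adjusted over the list alone were identical except for heat shock proteins (4 higher and 32 lower), flavonoid and stilbene genes (22 lower), rRNA-annotated models (1 higher and 42 lower) and green shoot markers (1 higher). The test called 1881 genes, 633 higher and 1248 lower (1661 without the 4 stretches). TPM scaling gave 882 and 944 and moved the median of all genes by 0.132 log2. camera called 18 lists, 1 with an estimated correlation.

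At 12 h the response of malate synthase Ah11g246200 differed by 10.56 ± 0.48, that of Ah06g434000 by 8.77 ± 0.37 and that of beta-galactosidase Ah06g251100 by -7.83 ± 0.30. Glyoxylate cycle genes (12 of 25, adjusted p = 8.6e-11) and mannose-binding genes (10 of 12, adjusted p = 5.4e-12) were enriched among those with the higher response in HY33. Among the 63 flavonoid and stilbene genes 10 were lower (adjusted p = 5.9e-07, and p = 0.37 with an estimated correlation), and of the 38 nitrogen assimilation genes 8 were higher and 2 were lower (adjusted p = 0.0027, and p = 0.3 with an estimated correlation). Of the 139 rRNA-annotated models 100 were lower and 1 was higher (adjusted p = 9.8e-47), and of the 31 root markers 4 were higher (adjusted p = 0.036, and p = 0.35 with an estimated correlation). Among the 13 plastid-genome-type genes 5 were lower and 1 was higher (adjusted p = 0.013, and p = 0.37 with an estimated correlation), with a median of -0.06 that turned to 0.05 with TPM scaling, and the 40 green shoot markers had a median difference of -0.35 log2 (adjusted p = 3.2e-06, and p = 0.37 with an estimated correlation). These list counts stayed as given when adjusted over the list alone except for flavonoid and stilbene genes (11 lower), nitrogen assimilation (9 higher and 2 lower), rRNA-annotated models (1 higher and 114 lower) and root markers (5 higher). Genes called numbered 1911, 971 higher and 940 lower. Without the 4 stretches they came to 1693 and the balance turned, with 817 higher and 876 lower, as it did with no fold threshold (3285 and 3378). Of the calls 50.8% were higher, and with TPM scaling 63.6%, the median of all genes moving by 0.118 log2. camera called 15 lists, 1 with an estimated correlation.

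At 24 h the response of Ah11g246200 differed by 13.79 ± 0.51, with 16 ± 1.51 FPKM in HY33 and 0.657 ± 0.155 in HY9115, and that of Ah06g251100 by -6.55 ± 0.33. Among 117 heat shock genes 7 were higher and 1 was lower (adjusted p = 2.5e-10), and of the 98 class III peroxidases 13 were higher and 3 were lower (adjusted p = 0.00011, and p = 0.23 with an estimated correlation). Among 87 suberin, cutin and wax genes 7 were lower and 3 were higher (adjusted p = 3e-04). Diterpenoid synthesis genes (16 of 30, adjusted p = 2e-17) were enriched among those with the lower response in HY33. Among the 139 rRNA-annotated models 51 were lower (adjusted p = 1.4e-23), and of the 13 plastid-genome-type genes 5 were lower and 1 was higher (adjusted p = 0.0073, and p = 0.25 with an estimated correlation). Of the 40 green shoot markers 1 was higher (adjusted p = 1.2e-06, and p = 0.28 with an estimated correlation), although their median was -0.25 and camera's direction down. When adjusted over the list alone, the counts did not move except for heat shock proteins (8 higher and 1 lower), class III peroxidases (14 higher and 3 lower), rRNA-annotated models (70 lower) and green shoot markers (1 higher and 1 lower). Called genes came to 1584, 788 higher and 796 lower (1452 without the 4 stretches). TPM scaling gave 661 higher and 989 lower. The near-even balance turned with quantile scaling (906 and 743), DESeq2 (886 and 782), the compared libraries alone (898 and 789), no filter (968 and 931) or an FPKM of 5 (566 and 488). It also turned with limma on log2(FPKM + 1) (570 and 531), with no fold threshold (2313 and 2142) and without the rRNA models (788 and 745), and was even with robust dispersions (781 and 781) and the replicate block (786 and 786). camera called 18 lists, 3 with an estimated correlation.

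At 48 h peroxidase and cell wall genes had the higher response in HY33. Among 98 class III peroxidases 31 were higher and 3 were lower (adjusted p = 2.7e-05, and p = 0.2 with an estimated correlation), and of the 127 cell wall expansion genes 27 were higher and 3 were lower (adjusted p = 0.0019, and p = 0.17 with an estimated correlation). Among 28 fermentation genes 8 were higher (adjusted p = 0.00011), and of the 84 proton pump genes 2 were higher and 1 was lower (adjusted p = 9.3e-05). Genes annotated with syncytium formation, an annotation that expansins carry, were enriched (17 of 25, adjusted p = 4.1e-13). Malate synthase Ah11g246200 differed by 11.08 ± 0.51 and the glycosyltransferase Ah01g058900 by 8.14 ± 0.64. Among 139 rRNA-annotated models 64 were lower (adjusted p = 4.5e-19), and of the 38 cotyledon markers 3 were lower and 2 were higher (adjusted p = 0.041, and p = 0.38 with an estimated correlation). Adjusted over the list alone, these counts were identical except for class III peroxidases (34 higher and 4 lower), cell wall genes (27 higher and 4 lower), proton pumps (2 higher and 2 lower) and rRNA-annotated models (78 lower). There were 3384 calls, 2134 higher and 1250 lower (3173 without the 4 stretches). TPM scaling gave 1601 and 1772 (median of all genes moved by -0.155 log2) and total counts 1725 and 1636 (-0.116). camera called 12 lists, 3 with an estimated correlation.

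Some fixed lists stand outside these accounts. At 3 h in HY33, of the 76 abscisic acid signalling genes 14 rose and 11 fell (adjusted p = 0.0017, and p = 0.19 with an estimated correlation), and of the 120 sodium and potassium transport genes 15 rose and 11 fell (adjusted p = 0.049, and p = 0.31 with an estimated correlation). Of the 27 WRKY factors 4 rose (adjusted p = 0.00088, and p = 0.12 with an estimated correlation), and of the 79 sugar and starch genes 15 fell and 7 rose (adjusted p = 0.032, and p = 0.19 with an estimated correlation). Of the 26 senescence genes 5 fell (adjusted p = 0.031, and p = 0.27 with an estimated correlation) in HY9115 at 3 h, and in the test of the difference in response at 12 h of the 192 MYB factors 12 were lower and 3 were higher (adjusted p = 0.039, and p = 0.35 with an estimated correlation). Nodule markers passed in no comparison: at 48 h in HY33 17 of 58 fell and 6 rose (adjusted p = 0.41). The plastid-genome-type genes, a further sign of RNA quality, held 0.031% ± 0.00275 of the counts in HY33 and 0.0312% ± 0.000451 in HY9115 at 0 h. In the same order the shares were 0.0323% ± 0.00259 and 0.0277% ± 0.000551 at 3 h, 0.0261% ± 7e-04 and 0.0356% ± 0.00422 at 12 h, 0.025% ± 0.000814 and 0.0333% ± 0.000557 at 24 h, and 0.0259% ± 0.00154 and 0.0289% ± 0.00225 at 48 h. Adjusted over the list alone, higher and lower counts differed for MYB factors (3 and 13).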

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

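All tests in this part were chosen after the result was seen, except those of the splits, of the scaling of green shoot markers and of the difference in response itself. The cultivars' changes from 0 h differed in 1881, 1911, 1584 and 3384 genes and 18, 15, 18 and 12 lists at 3, 12, 24 and 48 h by the test of the difference. Lists that held with an estimated correlation were heat shock genes at 3 h (2 higher, 32 lower) and 24 h (7 higher, 1 lower), suberin, cutin and wax genes at 24 h (3 higher, 7 lower), proton pumps (2 higher, 1 lower) and fermentation genes (8 higher) at 48 h, and rRNA-annotated models at 12 h (1 higher, 100 lower), 24 h (51 lower) and 48 h (64 lower).

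Single genes whose response differed were, in log2 units, Ah13g246900 (-7.16 ± 0.84), Ah06g251100 (-7.14 ± 0.31) and Ah06g434000 (6.95 ± 0.41) at 3 h. At 12 h they were Ah11g246200 (10.56 ± 0.48), Ah06g434000 (8.77 ± 0.37) and Ah06g251100 (-7.83 ± 0.30), at 24 h Ah11g246200 (13.79 ± 0.51) and Ah06g251100 (-6.55 ± 0.33), and at 48 h Ah11g246200 (11.08 ± 0.51) and Ah01g058900 (8.14 ± 0.64). Differences of a gene at several times reuse the same 0 h libraries, so they are not separate results. At 0 h Ah06g251100 stood at 0.113 ± 0.133 FPKM (4 counts) in HY9115. In HY33 Ah11g246200 then stood at 0.05 ± 0.0173 and Ah06g434000 at 0.0333 ± 0.0577 (4 counts each).

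Other splits of the same samples were refitted with the compared libraries alone. For the difference in response 40 of 200 splits were drawn per time, the real one among them. Only the real one, 1 of 40 and a share under 0.05, gave as many calls. It called 1884, 1799, 1687 and 3302 genes, against at most 1166, 1176, 1463 and 2264 in the others drawn. The others mix the cultivars, which widens their spread, so this cannot decide on chance. Undrawn splits were not fitted. The smallest share the test could give was 1 of 40. Chance differences between the plants sampled are not excluded. For the other 13 comparisons 10 splits are too few for a share under 0.05. There the real splits called 5871, 10063, 10051 and 14529 genes in HY33, 6222, 9889, 8367 and 15062 in HY9115 and 2425, 2414, 1434, 2154 and 3505 between cultivars, and the highest other split called 1 gene.

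The rRNA-annotated models had lower responses in HY33 at each time, but these 4 differences share the 0 h libraries, where the models already held 0.0556% of the counts in HY33 and 0.0126% in HY9115, and in salt the HY33 share was the lower only at 12 h (0.0514% and 0.118%). Uneven carry-over of rRNA between libraries cannot be told apart from a group difference: within groups the highest library share over the lowest had a median of 1.23 and ranged from 1.09 to 2.06, below the 1.5 it would need as a median but too high to exclude it. The 176 other ribosome production genes had a median difference in response at 12 h of 0.02 (95% interval -0.04 to 0.08). As mRNAs, they leave regulation of rRNA itself open. Without these models the counts of calls moved by less than 1.5 times.

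Green shoot markers fell at 48 h in both cultivars, with medians of -1.94 in HY33 and -1.82 in HY9115. A smaller share of shoot tissue would raise root and cotyledon markers alike, but root markers had medians of -1.06 (-2.16 to -0.44) and -1.65 (-2.78 to -0.7) and cotyledon markers of 1.04 and 2.46 (1.86 with 1 gene at its bound). The root list holds nitrate and iron uptake genes, which treatment itself may change. Scaling is argued against too, since other scalings gave medians of -1.82 or lower. Salt or time in solution stays open, and 48 h nominally keeps the 0 h time of day.

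In HY33 at 0 h neighbouring genes on chromosomes 12 and 14 were lower than in the other HY33 groups, and those on chromosomes 2 and 4 higher than in HY9115, with smaller differences in some later HY33 groups (-0.93 on chromosome 14 at 24 h). A chance run of unrelated genes is argued against. For the difference in response 0 of 100 gene-order shuffles gave a 21-gene running median as large as the highest at any time. At 0 h the cultivar peaks were -7.44, -2.91, 1.04 and 1.26 on chromosomes 12, 14, 2 and 4. These were picked for passing the shuffled maximum (0.61). A candidate explanation, as a hypothesis, is an exchange between the subgenomes carried by the plants of that group. Genes were matched by identical KO and GO function and process annotation, not by sequence. Genes on chromosome 4 matching those on chromosome 14 had a median difference in response at 12 h of -0.85 (-0.92 to -0.78, 77 genes). For chromosome 12 the median on chromosome 2 was -0.87 (-1.4 to -0.25, 14 genes). That interval reaches past the -0.5 an exchange needs, so there an exchange and its absence cannot be told apart. Both intervals treat neighbouring genes as independent. The matching stretches overlap those seen to be higher at 0 h, so these medians largely restate that observation and are no separate test. The libraries of an HY33 group differed by at most 0.22 on chromosome 12 while the groups lay between -4.76 and -0.02. This would be seen if the 3 libraries of a group drew on the same plants. If so, p-values that use HY33 groups would be too small for genes that vary between plants.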

How the results depend on the processing

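Tests with limma, with total counts and without the rRNA models or the 4 stretches were added after the data were seen. Of 364 recomputed counts of genes 320 stayed within 1.5 times the reported count and 44 moved further, and of 56 overlaps 46 and 10. Of 3145 list tests 2817 kept their side of the threshold, 291 lost it, 37 gained it and none turned direction in camera. All 3158 recomputed values of named genes kept side and direction, but these were chosen for large changes. Leaving out each replicate in turn moved no count past 1.5 times, from 5760 to 6106 genes in HY33 at 3 h and from 1646 to 2080 for the difference in response at 12 h. The most calls lost by 1 omission were 781 of 10067 in HY9115 at 12 h. The planned change of pseudocount was not run, since the count test has none. In list tests a prior count of 0.1 stood in. The effect of depth on genes with low counts was not analysed here.

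Requiring an FPKM of 5 leaves fewer genes to test, and the counts were 3908, 6272, 6104 and 9095 in HY33, 6229, 5047 and 9380 in HY9115 at 12, 24 and 48 h, 1344, 1432, 842, 1090 and 2095 between cultivars and 1176, 1054 and 2165 for the difference in response at 12, 24 and 48 h, with overlaps of 4722, 4281 and 7379 genes. limma on log2(FPKM + 1), which shrinks the changes of low genes, called 3666, 6686 and 6671 in HY33 and 3956, 6702 and 5284 in HY9115 at 3, 12 and 24 h, 1423, 1362, 889, 1032 and 1486 between cultivars and 2011 for the difference in response at 48 h, with overlaps of 2379, 4658 and 4211. With no fold threshold, which by construction adds genes, the counts were 19018, 25108, 24213 and 29446 in HY33, 17967, 24395, 22321 and 29456 in HY9115, 10534, 9480, 6194, 12426 and 17045 between cultivars and 5900, 6663, 4455 and 10046 for the difference in response, with overlaps of 11789, 18185, 17690 and 23680.

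Of 277 list calls 264 were kept with a prior count of 0.1, 248 with no filter, 256 with quantile scaling and 50 with an estimated correlation, where the cause was not tested. In no comparison did all 3 same-numbered pairs correlate above 0.1, which does not exclude a shared replicate effect. With the replicate block the counts were 5948, 10118, 10038 and 14541 in HY33, 6214, 10051, 8341 and 15101 in HY9115, 2401, 2452, 1582, 2143 and 3787 between cultivars and 1855, 1886, 1572 and 3341 for the difference in response, overlaps were 3777, 7252, 6701 and 11483, and 280 list calls were made, 276 of them shared with the reported ones.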

Other observations

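Tests in this part were chosen after the data were seen, except the enrichment tests and the edgeR test of HY33 at 12 h. Single genes with large decreases in HY33 included some of metal chelation and coumarin synthesis. The nicotianamine synthase Ah07g300600 was at least 102-fold lower at 12 h, and the dioxygenase Ah19g107400, annotated with coumarin synthesis, fell by 8.73 ± 0.26. Stilbene synthase genes, of the resveratrol branch, were enriched among those that rose, with trihydroxystilbene synthase activity at 25 of 26 genes in HY33 and 26 of 26 in HY9115 at 3 h (adjusted p = 1.3e-25 and 2.7e-26).

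Among genes that fell, microtubule-based movement, held by kinesin motors, was enriched at 48 h (71 of 108 in HY33, adjusted p = 6.3e-22, and 73 of 108 in HY9115, adjusted p = 7.1e-22), as was lipid catabolism (99 of 185, adjusted p = 4.3e-21, and 111 of 185, adjusted p = 1e-26) and secondary cell wall formation (83 of 123, adjusted p = 1.7e-26, and 93 of 123, adjusted p = 6.8e-34). Terpene synthase activity was enriched among genes higher in HY9115 at 24 h (8 of 16, adjusted p = 1.1e-06).

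The 30 clock genes had a median absolute log2 change of 1.47, 0.9, 0.85 and 0.83 in HY33 at 3, 12, 24 and 48 h, against 0.34, 0.48, 0.46 and 0.67 over all genes, and of 1.37, 0.71, 0.97 and 0.97 in HY9115, against 0.32, 0.47, 0.4 and 0.67. Time of day at harvest is not given in the sources used here. In a multidimensional scaling of the libraries the first pair of axes held 33.1% and 23.6% of the variance.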
